A study of Mus musculus with 9 samples.

How the data were processed

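RNA of nuclei from the ventricles of postnatal mouse hearts (C57BL6/J) was measured by single-nucleus Drop-seq, in which each nucleus is captured in a droplet with a barcoded bead that primes on poly(A) tails. Per the labels' protocols, hearts came from controls, heterozygous for ERRα and wild type for ERRγ, and from mice with both genes knocked out. ERRα and ERRγ are nuclear receptors that switch on genes of mitochondrial energy metabolism, and the files list them as Esrra and Esrrg. There were 9 libraries, 3 from controls at postnatal day 6 (control P6), 3 from controls at postnatal days 9 to 10 (control P10) and 3 from knockouts at the same stage (KO P10). Ventricles were processed fresh or frozen before nuclei were isolated, per the labels' protocols, without a record of which library was treated in which way. The labels give no batch.

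The deposited values were whole-number UMI counts per gene and barcode, with no normalization recorded, and 0 values were negative or not whole. The authors aligned reads to mm10 with STAR 2.5.2a, per the submitters' processing notes, and the deposited tables count exonic and intronic reads together, per the names of the files. The rule by which 3000 barcodes were kept in each P6 library and 4000 in each P10 library, the gene annotation and the use of strand were not recorded. Without strand, reads of a gene and of an antisense neighbour cannot be told apart, and reads of near-identical copies such as ribosomal protein pseudogenes cannot be assigned with certainty. Gene positions were taken from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes, and are 1-based.

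Mitochondrially encoded genes were left out of all sums and of the clustering, and barcodes with under 500 remaining UMIs were left out. In KO P10 library 2, barcodes found also in KO P10 library 1 were left out, except from sums over all barcodes, a choice made after the data were examined. Scrublet scores (scanpy 1.11.5) were computed per library, and the nuclei with the highest 5% of scores in each library were left out as candidate doublets. Counts were scaled to 1000 per nucleus and log-transformed. The 2000 most variable genes among genes found in at least 10 nuclei were centred within each library, which removes differences between libraries in mean level from the clustering. The first 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9, seed 1) gave the clusters. Computations used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

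Clusters were named from markers of 13 classes fixed before the data were examined. A name required a positive mean log2 of the markers over the mean of all clusters, with at least 3 markers raised 1.5-fold. A cluster stayed unnamed if a rival class had a mean log2 above both 0.5 and 0.5 times that of the best class. Endothelial, endocardial and lymphatic endothelial classes were not rivals of each other, nor pericytes of smooth muscle or macrophages of lymphocytes. A threshold set after the data were examined kept unnamed any cluster whose Malat1 level, an RNA retained in nuclei, was under 40% of the median over clusters. Named classes are called cardiomyocyte-like and so on. A class was tested if each of the 9 libraries held at least 50 of its nuclei, which left cardiomyocyte-like, fibroblast-like, endothelial-like and endocardial-like nuclei. Nuclei are not replicates, so counts were summed per library over the nuclei of a class, and additionally over all barcodes of a library.

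Sums were compared with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), two-sided, in 1 fit of all 9 libraries with the group as the only term, TMM factors and filterByExpr. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and 0.05 was the threshold. Each comparison asked either how controls differed between P6 and P10 or how knockouts differed from controls at P10. Whether the genotype effect differed between classes was tested as a class by genotype interaction on class sums with the library as a block. Levels are the CPM values of edgeR, which scale counts to a common class total with TMM factors, given as mean ± SD over 3 libraries, and log2 fold changes are given with their standard errors (SE).

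Fixed before the data were examined were 15 lists: fatty acid oxidation, respiratory chain, TCA cycle and pyruvate dehydrogenase, mitochondrial regulators and dynamics, glycolysis and glucose uptake, calcium handling and excitation, sarcomere of the maturing heart, fetal and neonatal heart genes, cell cycle, integrated stress response, extracellular matrix, angiogenesis, endothelial fatty acid handling, hypoxia response, and immediate early and heat shock genes. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over lists and classes. The same test with a correlation estimated from the libraries, and fry, which asks whether the genes of a list move on balance one way, stood beside it. Ribosomal protein genes, Malat1, Ttn and hemoglobin RNA were followed as signs of RNA quality and of RNA from other cells.

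The genes named were drawn from those chosen by a rule fixed before the data were examined, and not every gene chosen is printed. In cardiomyocyte-like nuclei they were the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 50 CPM in the higher group and no overlap between the libraries of the groups. In each other class they were 4 and 4 by the same rule, restricted to genes at least as high in that class as in cardiomyocyte-like nuclei. Up to 4 members of each list with the smallest p were added, with matrix genes taken in fibroblast-like nuclei and the angiogenesis and endothelial fatty acid lists in endothelial-like nuclei. Esrra, Esrrg, Ppargc1a, Gdf15, Myh6, Myh7, Nppa and Nppb were always named. The ranking left out predicted genes, mitochondrially encoded genes, and Xist and Y-linked genes. Ribosomal protein genes were counted as those named Rpl or Rps followed by a number, so Rplp0 is not among them.

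Shares of nuclei were compared with a two-sided exact permutation test over libraries, whose smallest possible p for 3 against 3 is 0.1, and with edgeR on the numbers of nuclei. The relation of the genotype change to the change with age was given as a correlation and a covariance across genes, beside 20 simulations of unchanged groups that share the control P10 libraries.

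The tests were tested on simulated counts drawn from the means and library sizes of each class. In simulated cardiomyocyte-like sums of 11762 genes, 59 of 66 genes changed 4-fold, 12 of 67 changed 2-fold and 0 of 67 changed 1.5-fold were recovered, with 5 false calls among 76. For fibroblast-like sums of 8115 genes, 57 of 66 genes changed 4-fold and 10 of 67 changed 2-fold were recovered. For endothelial-like sums of 6209 genes the numbers were 50 of 66 and 13 of 67, and for endocardial-like sums of 4265 genes 55 of 66 and 12 of 67. The interaction test recovered 87 of 135 simulated genes with 9 false calls.

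The alternatives tried were the size factors and the Wald test of DESeq2 1.42.0, no filter on low counts, thinning to the smallest library, fits of 6 libraries, the replicate number as a block, leaving out each library, a minimum of 800 UMIs, no removal of doublets, Leiden resolution 0.5, classes from marker UMIs of single nuclei, clustering without the genes called, camera with an estimated correlation, fry, limma in place of the block in the interaction test, Spearman correlation, and genes of at least 50 CPM. Added after the data were examined were a term for the sex of the library, mitochondrial genes kept, shared barcodes kept, a pair of libraries left out together, clusters added to or left out of the cardiomyocyte-like class, named nuclei as the denominator of shares, and the relation without ribosomal protein genes and genes called in fibroblast-like nuclei.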

Results

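The data were 9 libraries of nuclei from mouse ventricles: 3 from controls at P6, 3 from controls at P10 and 3 from ERRα/ERRγ knockouts (KO) at P10. The comparisons addressed how cardiac cell types mature after birth and how that maturation differs without ERRα and ERRγ. The control P6 libraries 1 to 3 held 2608067, 3745640 and 2983541 UMIs, the control P10 libraries 4949999, 5344130 and 5214758, and the KO P10 libraries 5769630, 5184307 and 4130387. Of 33000 barcodes, 5897 had under 500 UMIs, 464 in KO P10 library 2 were shared with library 1, and 1328 were left out as candidate doublets. The remaining 25311 nuclei numbered 1788 to 3682 per library, with a median of 739 to 941 UMIs and 531 to 657 genes. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between libraries.

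Sex was not recorded in the labels, and the libraries differed in sex-linked RNA. Xist, transcribed from the inactive X chromosome, had 4656, 8297 and 7232 UMIs in the control P6 libraries, with 29 to 35 UMIs of Y-linked genes. Control P10 library 1 and KO P10 library 1 had 1934 and 5750 Xist UMIs with 12 Y-linked UMIs each. Control P10 libraries 2 and 3 had 1975 and 1818 Y-linked UMIs with 5 and 2 of Xist, and KO P10 library 3 had 1492 with 3 of Xist. Outside the shared barcodes, KO P10 library 2 had 1702 Y-linked UMIs and 6 of Xist. The groups at P10 thus had alike compositions, whereas all control P6 libraries were of the Xist-high kind.

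Clustering gave 17 clusters. Markers named 10951 cardiomyocyte-like nuclei (865 to 1600 per library), 4234 fibroblast-like (263 to 734), 1677 endothelial-like (59 to 323) and 1381 endocardial-like nuclei (63 to 302). Cardiomyocyte-like sums held 992140 to 1980931 UMIs per library, fibroblast-like sums 211429 to 664865, endothelial-like sums 47076 to 370489 and endocardial-like sums 59798 to 293133. With libraries pooled, different clusters held most cardiomyocyte-like nuclei of each group: cluster 2 held 64.6% at control P6, cluster 1 held 71.6% at control P10 and cluster 4 held 72.6% at KO P10. Control P6 library 1 departed from its group, with 111 of 911 cardiomyocyte-like nuclei in cluster 2 and 704 in cluster 11. Cycling genes such as Ect2 and Kif15 led cluster 10 of this class, and Neil3 and Top2a led cluster 14 of the fibroblast-like class. Unnamed clusters low in Malat1 took 11.02% ± 2.43 of nuclei at control P6, 22.3% ± 7.18 at control P10 and 33.2% ± 10.3 at KO P10 (SD, n = 3). Cluster 3, led by hemoglobin and macrophage RNA such as Hba-a1 and Lyz2, held 0.735%, 4.23% and 23.5% of nuclei in the 3 groups. Cluster 5, led by Cox7a1 and pseudogenes, held 9.48%, 16.4% and 0.339%, and cluster 8, led by Acta1 and Nppa, held 0.798%, 1.66% and 9.43%.

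Signs of RNA quality and of RNA from other cells moved with the groups, for Ttn and Malat1 with overlap between control P10 and KO P10 libraries. Ttn, a cardiomyocyte gene, made up 0.0860% of UMIs in fibroblast-like nuclei at control P6, 0.490% at control P10 and 0.622% at KO P10, against 0.910%, 1.82% and 1.77% in cardiomyocyte-like nuclei. In fibroblast-like nuclei it ranged from 0.349% to 0.675% at control P10 and from 0.412% to 0.877% at KO P10. Ribosomal protein genes made up 0.586% of cardiomyocyte-like UMIs at control P6, 0.253% at control P10 and 0.674% at KO P10, and 1.36%, 0.507% and 1.08% in fibroblast-like nuclei. Malat1 made up 17.4%, 12.0% and 11.2% of cardiomyocyte-like UMIs. The hemoglobin gene Hbb-bs made up 0.0911%, 0.113% and 0.378% ± 0.335 of them (SD, n = 3). Mitochondrially encoded genes took 1.55%, 22.4% and 10.2% of all UMIs, with 40.8% in control P10 library 1.

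The targeted genes were read first. Esrra (chromosome 19, 6910977 to 6921813, minus strand) had 94, 209 and 152 UMIs in cardiomyocyte-like nuclei of the control P6 libraries, 89, 209 and 134 at control P10, and 16, 35 and 24 at KO P10. These corresponded to 106, 102 and 73.2 CPM at control P10 and 9.28, 24.96 and 21.5 CPM at KO P10, a log2 fold change of −2.35 ± 0.32 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000338). Esrrg (chromosome 1, 187608791 to 188214885, plus strand) stood at 647, 857 and 496 CPM at control P6, 1967, 1269 and 1658 CPM at control P10, and 793, 685 and 791 CPM at KO P10. It rose with age in controls (log2 1.29 ± 0.28, edgeR adjusted p = 0.00510) and was lower in KO (log2 −1.11 ± 0.28, adjusted p = 0.0173). The Esrrg call ended without control P10 library 3 (log2 −1.10), KO P10 library 2 (log2 −1.04) or KO P10 library 3 (log2 −1.15). Which part of each gene was deleted was not stated, so intronic and 3′ counts may come from outside it and remaining counts do not measure functional RNA. Ppargc1a, a coactivator of these receptors, differed between KO and control P10 by log2 0.01 ± 0.53 (adjusted p = 0.992).

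Between P6 and P10, channel genes such as Kcnd2 and Cacna1c rose and the contractile protein genes Tnni1 and Tpm2 fell in control cardiomyocyte-like nuclei. Pdzrn4 (chromosome 15, 92396881 to 92771819) rose from 66.8 ± 17.0 to 754 ± 107 CPM (SD, n = 3; log2 3.48 ± 0.29, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.21e-05). Kcnd2, a potassium channel of cardiac repolarization, rose from 382 ± 164 to 2670.2 ± 937 CPM (log2 2.81). Cacna1c (chromosome 6, 118587240 to 119196418), the pore of the L-type calcium channel, rose from 2445 ± 985 to 8665 ± 3005 CPM (log2 1.83). Tnni1 (chromosome 1, 135779434 to 135810989), the troponin I of the fetal heart, fell from 559.6 ± 104 to 82.6 ± 22.9 CPM (log2 −2.76 ± 0.31, adjusted p = 0.000116). The tropomyosin gene Tpm2 fell from 156 ± 81.1 to 23.7 ± 9.58 CPM. Of 11922 genes tested, 1074 rose and 1148 fell. The other largest rises were those of Cyyr1 (log2 2.97), Rgs7 (2.94), Col15a1 (2.75), Abca8a (2.69), C1qtnf7 (2.599) and Fgf14 (2.57). The other largest falls were those of Tmigd1 (−3.01), Tspear (−2.83), Rpl36 (−2.76), Vwa1 (−2.71), Frmd5 (−2.68) and the small nucleolar RNA Snord104 (−2.67). Pdzrn4, Fgf14 and Rgs7 were also leading genes of cluster 1 and Kcnd2 of cluster 9, and Vwa1, Tmigd1, Tspear and Frmd5 led cluster 11, of whose 817 nuclei 704 came from control P6 library 1. Col15a1, Abca8a and C1qtnf7 stood far higher in fibroblast-like nuclei of control P10, at 1139, 1404 and 1062 CPM against 117, 112 and 61.7 CPM in cardiomyocyte-like nuclei. Myh6 and Myh7, the adult and fetal myosin heavy chains of the mouse ventricle, differed by log2 −0.45 ± 0.34 (adjusted p = 0.378) and −0.30 ± 0.40 (adjusted p = 0.635). Leaving out control P6 library 2 or 3, or control P10 library 1 or 3, gave 1067, 878, 1402 and 1113 genes called, and classing nuclei by their own marker UMIs gave 1370.

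The list of calcium handling and excitation rose with age in these nuclei, with 8 of 24 measured members up and 0 down (9 and 0 adjusted over the list alone; camera adjusted p = 0.000130, adjusted p = 0.344 with an estimated correlation). Besides Kcnd2 and Cacna1c these included the calcium channel subunit gene Cacnb2 (log2 1.31) and the potassium channel gene Kcnq1 (log2 1.25). The same list also rose in fibroblast-like, endothelial-like and endocardial-like nuclei, so its rise was not particular to cardiomyocyte-like nuclei. In the respiratory chain list 10 of 49 members fell and 0 rose (12 adjusted over the list alone; adjusted p = 6.36e-05, adjusted p = 0.664 with an estimated correlation). They included Uqcrc1 (log2 −1.83), Ndufab1 (−1.37) and Atp5h (−1.26). In the glycolysis and glucose uptake list 3 of 21 fell, the same 3 over the list alone (adjusted p = 0.0322, adjusted p = 0.705 with an estimated correlation). Eno1 (log2 −1.75) and Eno3 (−0.97) fell, whereas Gapdh, at 1.76 CPM at control P10, shares reads with pseudogene copies. The integrated stress response list had 5 of 15 members down and 0 up, likewise 5 over the list alone (adjusted p = 0.0174, adjusted p = 0.394 with an estimated correlation). Among them were the transcription factor Atf4 (log2 −1.02) and the cystine transporter subunits Slc7a11 (−1.42) and Slc3a2 (−1.36). These falling lists moved with the ribosomal protein genes, of which 54 of 68 fell and 0 rose (camera p = 0.0487 with an estimated correlation). In the cell cycle list Pola1 rose (log2 1.18) and Tyms fell (log2 −1.04), each of 32 measured and also over the list alone, with the list lower (adjusted p = 0.0227, adjusted p = 0.744 with an estimated correlation). Extracellular matrix genes rose in 21 of 30 cases and fell in 1 (25 and 2 adjusted over the list alone; adjusted p = 1.84e-11, adjusted p = 0.0743 with an estimated correlation). Angiogenesis genes rose in 8 of 17 and fell in 0 (11 and 1 over the list alone; adjusted p = 2.84e-05, adjusted p = 0.205 with an estimated correlation). Matrix and vessel genes such as Col1a2 (log2 1.48), Dcn (1.61) and Flt1 (2.11) are markers of fibroblasts and endothelial cells. Without control P6 library 2, 4 of the 15 lists were called in place of 7.

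Other lists showed no call as a whole by camera over the same interval. Of 28 fatty acid oxidation genes 1 rose, the fatty acid transporter gene Cd36 (log2 1.03), and 2 fell, Cpt1b (−0.68) and Acadvl (−0.67), but 0 passed in either direction when adjusted over the list alone (camera adjusted p = 0.925). Of 22 genes of the TCA cycle and pyruvate dehydrogenase 4 fell and 0 rose, also over the list alone, among them Pdhb (log2 −1.45) and Idh3b (−1.11), with a list median of 0.02 and a mean of −0.09 (adjusted p = 0.830). Mitochondrial regulators and dynamics rose in 5 of 24 cases and fell in 2, in both scopes of adjustment, with Mcu, the mitochondrial calcium uniporter, at log2 1.10 and Polg, the mitochondrial DNA polymerase, at −1.33 (camera adjusted p = 0.0676). Fry called this list upward (adjusted p = 0.0223). In the sarcomere list 1 of 22 members rose and 3 fell in either scope (adjusted p = 0.471), Tnnc1, cardiac troponin C, falling from 4192 ± 783 to 778 ± 232 CPM. Of the fetal and neonatal heart genes 2 of 22 rose and 2 fell in either scope (adjusted p = 0.176), Igf2bp3 falling by 1.14 on the log2 scale beside Tnni1 and Acta2 rising by 1.48. The hypoxia response list had 2 of 18 members up, Egln3 (log2 1.70) and Egln1 (0.99), and 0 down (adjusted p = 0.300). In the list of immediate early and heat shock genes Hspb1 alone changed among 12 (log2 −2.15; median 0.00 and mean 0.17, with camera tending downward, adjusted p = 0.775). In the endothelial fatty acid list 3 of 10 rose and 2 fell (5 and 3 over the list alone; adjusted p = 0.287). The changes of Cd36, Cpt1b, Acadvl, Idh3b, Polg, Igf2bp3 and Atf4 did not pass without control P6 library 2, nor that of Eno3 without control P6 library 3.

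**Figure D1:**
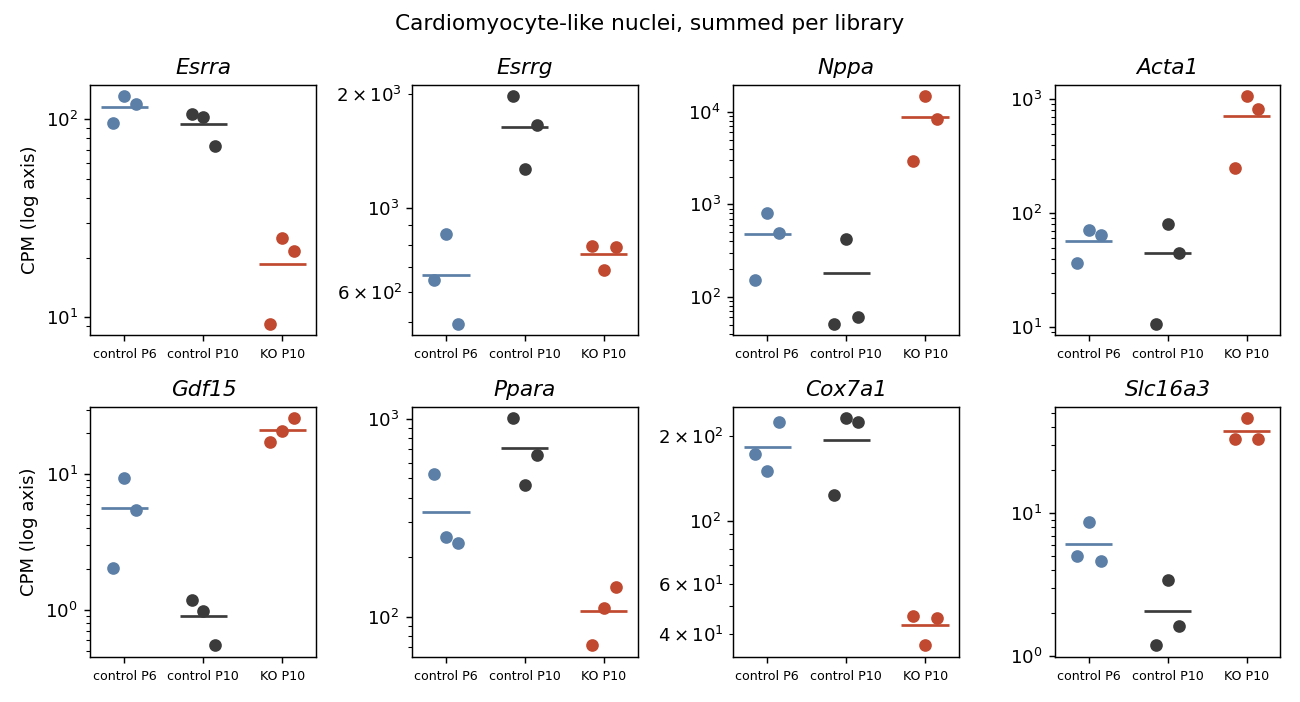
CPM in cardiomyocyte-like nuclei (log axis) of 8 genes, with 1 point per library and a line at the mean of each group. Nppa, Acta1, Gdf15 and Slc16a3 stood higher and Esrra, Esrrg, Ppara and Cox7a1 lower in every KO P10 library than in every control P10 library.

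In KO cardiomyocyte-like nuclei, Nppa, Myl7 and Acta1 were among the genes that rose and Ppara among those that fell. Nppa (chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, rose from 180.0 ± 214 to 8715 ± 5892 CPM (SD, n = 3; log2 5.58 ± 0.86, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.000954). Myl7 (chromosome 11, 5896637 to 5898782), the atrial myosin light chain, rose from 10.5 ± 2.37 to 175 ± 49.6 CPM (log2 4.03 ± 0.32, adjusted p = 8.23e-06). Acta1 (chromosome 8, 123891769 to 123894751), skeletal muscle actin, rose from 45.1 ± 34.5 to 712 ± 417 CPM (log2 3.91 ± 0.55, adjusted p = 0.000433). Ppara (chromosome 15, 85734983 to 85802819), the nuclear receptor that drives fatty acid oxidation genes, fell from 709.7 ± 277 to 107 ± 34.7 CPM (log2 −2.73 ± 0.37, adjusted p = 0.000408). Of 11922 genes tested, 710 rose and 653 fell. Other large rises were those of the glutamate receptor subunit Grin2c (log2 3.84), the calcium release channel Ryr3 (3.75), the ubiquitin ligase Trim47 (3.72) and the metallothionein Mt2 (3.53). Other large falls were those of Lrtm1 (−4.44), Wdr72 (−4.15), Plekhh1 (−3.69), the integrin subunit Itgb6 (−3.63), Rgs7 (−2.71) and Rap1gap2 (−2.57). Itgb6, Ppara and Rgs7 were also among the leading genes of cluster 1, and Ryr3 of cluster 4, so these differences follow the clusters that held most nuclei of each group. Leaving out control P10 library 3 or KO P10 library 3 gave 428 and 724 genes called. Classing nuclei by their own marker UMIs gave 819, and adding the low-Malat1 cluster 8, led by Acta1 and Nppa, gave 2335.

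The lists of energy metabolism were lower in KO cardiomyocyte-like nuclei. Of 22 genes of the TCA cycle and pyruvate dehydrogenase 5 fell and 0 rose (8 adjusted over the list alone; camera adjusted p = 8.59e-06, adjusted p = 0.333 with an estimated correlation), among them Dlst (log2 −1.25), Sucla2 (−1.05), Dlat (−0.96) and Got2 (−0.91). Mitochondrial regulators and dynamics fell in 5 of 24 cases and rose in 0, in both scopes of adjustment (adjusted p = 0.000173, adjusted p = 0.157 with an estimated correlation). Besides Ppara, the fusion protein gene Mfn1 fell (log2 −1.72), the mitochondrial RNA-binding protein gene Lrpprc (−1.02) and the mitochondrial creatine kinase gene Ckmt2 (−1.71). In the respiratory chain list 4 of 49 fell and 0 rose in both scopes (adjusted p = 0.0196, adjusted p = 0.720 with an estimated correlation). It was led by Cox7a1 (chromosome 7, 30184144 to 30186078), a muscle subunit of cytochrome c oxidase, which fell from 194 ± 60.4 to 42.8 ± 5.59 CPM (log2 −2.18 ± 0.28), and followed by Atp5l (−1.23), Cycs (−1.13) and Ndufs1 (−0.79). Cox7a1 also led the unnamed low-Malat1 cluster 5, which held 16.4% of nuclei at control P10 and 0.339% at KO P10. Whether free RNA from such droplets takes part in the fall of Cox7a1 was not tested. Of 28 fatty acid oxidation genes 2 fell and 0 rose in both scopes (adjusted p = 0.0212, adjusted p = 0.492 with an estimated correlation). These were the fatty acid transporter gene Slc27a1 (log2 −1.82) and Cpt1b (−1.11), which admits fatty acids to mitochondria. Calcium handling and excitation genes fell in 6 of 24 cases and rose in 1, in both scopes (adjusted p = 0.00133, adjusted p = 0.275 with an estimated correlation). Kcnj3 (log2 −2.10), Hrc (−1.35) and Kcnq1 (−1.21) fell and Fgf12 (1.94) rose. Angiogenesis genes fell in 3 of 17 cases, among them Nrp1 (log2 −1.51), and rose in 0 in both scopes (adjusted p = 0.00519, adjusted p = 0.273 with an estimated correlation). The endothelial fatty acid list had 1 of 10 up and 1 down in both scopes (adjusted p = 0.576). In the cell cycle list 0 of 32 genes passed the edgeR test in either scope, although the list as a whole was lower (adjusted p = 0.00167, adjusted p = 0.643 with an estimated correlation). Its members with the smallest p were the replication genes Mcm5 (log2 −1.49, adjusted p = 0.142) and Hells (−0.84, adjusted p = 0.155), and KO P10 library 2 held 0 of 1286 cardiomyocyte-like nuclei in the cycling cluster 10. KO P10 libraries 1 and 3 held 6.72% and 8.11% of theirs there, against 4.51%, 8.63% and 5.13% in the control P10 libraries. Fewer cycling nuclei were thus a trait of KO P10 library 2 and not of the KO group.

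By camera with the preset correlation, fetal, glycolytic and stress response lists were higher in KO cardiomyocyte-like nuclei. However, fry gave adjusted p = 0.203 for the glycolytic list. It gave 0.229 for hypoxia response and 0.242 for immediate early and heat shock genes, described below. Of 22 fetal and neonatal heart genes 10 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2.83e-07, adjusted p = 0.218 with an estimated correlation). They included Nppa, Acta1, Myl7, the atrial light chain gene Myl4 (log2 1.88) and the natriuretic peptide gene Nppb (2.75). The integrated stress response list had 8 of 15 members up and 0 down (9 over the list alone; adjusted p = 4.99e-05, adjusted p = 0.190 with an estimated correlation). Among these, Gdf15 (chromosome 8, 70629393 to 70632456), a secreted stress cytokine, rose by log2 4.50 ± 0.57 (edgeR adjusted p = 0.000230) from 1, 2 and 1 UMIs in the control P10 libraries to 30, 29 and 29 at KO P10. The serine synthesis gene Psat1 (log2 2.97) and the folate enzyme genes Mthfd2 (3.05) and Mthfd1l (1.76) rose with it, the first of these from 1 to 3 UMIs per control P10 library. Glycolysis and glucose uptake genes rose in 6 of 21 cases and fell in 1 (9 and 1 over the list alone; adjusted p = 0.00696, adjusted p = 0.536 with an estimated correlation). The lactate exporter gene Slc16a3 (chromosome 11, 120948480 to 120960868) went from 1, 7 and 3 UMIs to 57, 65 and 37 (log2 3.98 ± 0.42, adjusted p = 6.27e-05). The muscle enzymes Pgam2 (log2 1.68) and Eno3 (1.28) and lactate dehydrogenase A, Ldha (1.05), rose. Of 18 hypoxia response genes 4 rose and 1 fell (5 and 1 over the list alone; adjusted p = 0.0256, adjusted p = 0.508 with an estimated correlation). Bnip3 (log2 1.69), Hif1a (1.10) and P4ha1 (0.85) were among those up. Extracellular matrix genes rose in 8 of 30 cases and fell in 1 (11 and 1 over the list alone; adjusted p = 0.000116, adjusted p = 0.235 with an estimated correlation), with Ctgf (log2 2.89) and Lox (2.37) up. Without TMM factors, at KO P10 Ctgf stood at 259 CPM in cardiomyocyte-like and 537 in fibroblast-like nuclei, and Lox at 56.6 and 356 CPM. In the list of immediate early and heat shock genes Hspb1 rose among 12 (log2 2.46; 2 over the list alone; adjusted p = 0.00995, adjusted p = 0.492 with an estimated correlation). In the sarcomere list the chaperone gene Cryab rose among 22 (log2 1.77; adjusted p = 0.0669). These rises moved with ribosomal protein genes, of which 37 of 68 rose and 0 fell (camera p = 0.0592 with an estimated correlation). Of the genes named here, Nppa, Acta1, Myl7, Myl4, Nppb, Pgam2, Eno3, Ldha, Ctgf, Lox, Hspb1 and Cryab also rose in fibroblast-like and endothelial-like nuclei. The rises of those genes are thus not particular to cardiomyocyte-like nuclei, and a part of free RNA in the droplets was not told apart. Without control P10 library 3 the calls of Sucla2, Dlat, Got2, Ndufs1, Cycs, Ckmt2, Hrc, Ldha, Mthfd1l, Bnip3, Hif1a, P4ha1 and Nppb ended, and those of Kcnq1, Got2, Ndufs1 and P4ha1 did without KO P10 library 3.

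**Figure D2:**
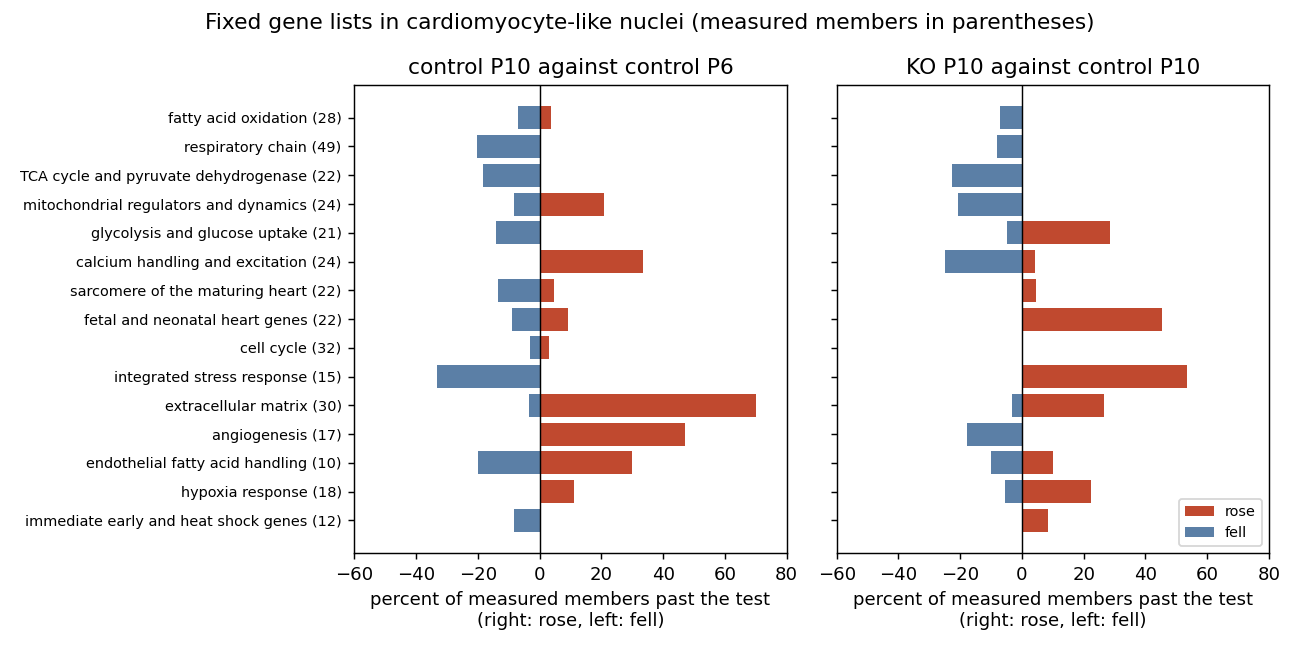
Percent of the measured members of each of the 15 lists that rose (right) or fell (left) in cardiomyocyte-like nuclei, for control P10 against control P6 and for KO P10 against control P10, with the number measured in parentheses. Matrix genes rose in 21 of 30 cases with age, and 8 of 15 stress response genes and 10 of 22 fetal and neonatal heart genes rose in KO.

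Genes that passed in both comparisons of cardiomyocyte-like nuclei mostly had opposite directions. Of 2222 genes that changed with age, 408 also passed in KO, and 364 of these (89.2%) went the other way. For example, Rgs7 rose with age and fell in KO, Gdf15 and Hspb1 fell with age and rose in KO, and Pdzrn4 stood at 273 ± 71.7 CPM in KO, between its levels at control P6 and control P10. The fall of Gdf15 with age did not pass without control P6 library 2 or control P10 library 3. Among genes that rose with age 178 fell in KO, against 58.8 for independent lists, and among genes that fell with age 186 rose in KO, against 68.4. The genes moving the same way numbered 21 upward and 23 downward, against 64.0 and 62.9. Across the 11922 genes, which are not independent replicates, Pearson's r of the fold changes was −0.306 and Spearman's rho −0.336. Control P10 libraries enter both comparisons with opposite sign, and unchanged groups sharing them gave r = −0.492 ± 0.00797 and rho = −0.469 ± 0.00788 (SD, 20 simulations), both stronger than observed. Their covariance was −0.0669 ± 0.00151 against −0.206 observed, a difference of −0.139. Simulated genes were drawn independently, so these SDs leave out shifts shared by many genes. The 3 control P10 libraries cannot be divided into parts of at least 2, so part of the overlap may come from sharing them, and r was −0.469 without control P10 library 2 and −0.231 without KO P10 library 3.

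**Figure D3:**
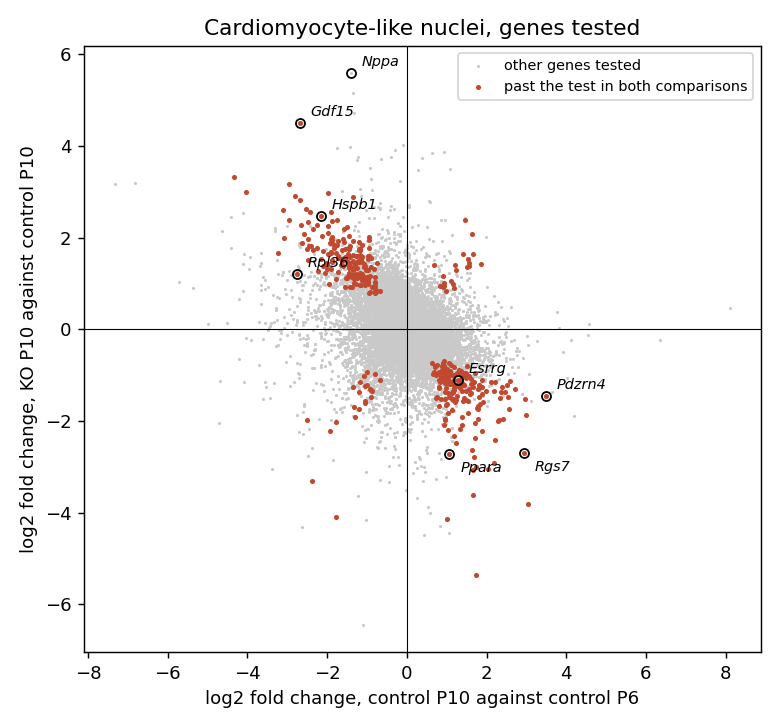
Log2 fold change of KO P10 against control P10 (vertical axis) over that of control P10 against control P6 (horizontal axis) for the 11922 genes tested in cardiomyocyte-like nuclei, with the 408 genes that passed in both comparisons in colour. Of these 364 lie in the quadrants of opposite direction.

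In fibroblast-like nuclei of controls, Cmah, Slc13a3 and Hmcn2 rose and Meg3 and Tagln fell between P6 and P10. Cmah, which modifies sialic acid, rose from 17.5 ± 9.01 to 194 ± 68.0 CPM (SD, n = 3; log2 3.52 ± 0.48, edgeR Benjamini-Hochberg adjusted p = 0.000329), the dicarboxylate transporter Slc13a3 (chromosome 2, 165405028 to 165473230) from 21.1 ± 4.63 to 147 ± 44.5 CPM, and Hmcn2 (chromosome 2, 31314415 to 31460738), a hemicentin of the extracellular matrix, from 49.3 ± 22.0 to 299.9 ± 10.2 CPM. The imprinted noncoding RNA Meg3 fell from 249 ± 43.8 to 21.6 ± 8.76 CPM and the smooth muscle gene Tagln from 58.5 ± 21.0 to 4.60 ± 4.75 CPM. Of 8177 genes 494 rose and 512 fell, C1qtnf1 (log2 2.604) and the pseudogenes Rps25-ps1 (−3.67) and Rps26-ps1 (−3.29), whose reads may belong to their parent genes, being the other largest. Genes of calcium handling and excitation rose in 14 of 18 cases (17 adjusted over the list alone; camera adjusted p = 6.36e-15, adjusted p = 0.132 with an estimated correlation) and sarcomere genes in 10 of 22 (11 over the list alone; adjusted p = 2.76e-07, adjusted p = 0.368 with an estimated correlation). These were cardiomyocyte genes such as Ryr2 (log2 2.15) and Ttn (2.55), and moved with the rising share of Ttn in fibroblast-like nuclei. Of 58 ribosomal protein genes 46 fell. In the extracellular matrix list Tnc, an adhesion protein of remodelling tissue, fell by 1.11 on the log2 scale among 30 (0 over the list alone; adjusted p = 0.149). The number of genes called was 1548 without control P6 library 1, 353 and 302 without control P6 library 2 and 3, 645 and 369 without control P10 library 1 and 3, and 497 with a term for the sex of the library. It was 602 after thinning, 510 with at least 800 UMIs per nucleus and 270 with classes from marker UMIs.

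In KO fibroblast-like nuclei, Hmcn2 and Cmah fell, and Ctgf and the heart muscle genes Nppa and Acta1 rose. Hmcn2 fell from 299.9 ± 10.2 to 8.81 ± 7.71 CPM (log2 −4.88 ± 0.42, edgeR Benjamini-Hochberg adjusted p = 2.4e-06), Cmah from 194 ± 68.0 to 16.5 ± 15.3 CPM (log2 −3.36), and Tll2 (−3.48) and Efhd1 (−3.14) followed. Ctgf, a matricellular growth factor, rose from 58.5 ± 25.8 to 594 ± 388 CPM (log2 3.23 ± 0.46, adjusted p = 0.000592). The elastin gene Eln (log2 2.46), the crosslinking enzyme gene Lox (2.19) and Mgp (1.58), an inhibitor of calcification, also rose, so that 5 of 30 matrix genes were up and 0 down in both scopes (camera adjusted p = 0.0113, adjusted p = 0.531 with an estimated correlation). Nppa rose from 165 to 11021 CPM (log2 5.99), Acta1 (4.39) and Myl7 (4.10) likewise, and Fmo2, a flavin monooxygenase, rose by log2 3.92. With them, 8 of 21 fetal and neonatal heart genes rose (13 and 1 down over the list alone; adjusted p = 8.57e-12, adjusted p = 0.157 with an estimated correlation) and 3 of 15 glycolysis genes (6 over the list alone; adjusted p = 0.000173, adjusted p = 0.275 with an estimated correlation). The ambient reference Hbb-bs, which fibroblasts lack, made up 0.175% of their UMIs at control P10 and 0.732% ± 0.708 at KO P10, where library 2 had 1.55% and libraries 1 and 3 had 0.326% and 0.320%. In the same nuclei 17 of 58 ribosomal protein genes rose. Of 8177 genes 137 rose and 104 fell. That total of 241 became 129, 58, 140 and 119 without control P10 library 1, control P10 library 3, KO P10 library 2 and KO P10 library 3, and the calls of Eln, Lox, Mgp and Fmo2 ended without control P10 library 3, those of Eln and Mgp also without control P10 library 1. It was 379 without a filter on low counts, 121 with at least 800 UMIs per nucleus, 33 with classes from marker UMIs and 71 without control P10 library 1 and KO P10 library 2 together.

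In endothelial-like nuclei of controls, Fabp5, Gpihbp1 and Apln were among the genes that fell between P6 and P10. Fabp5 (chromosome 3, 10012548 to 10016607), a fatty acid binding protein, fell from 685 ± 227 to 82.2 ± 49.8 CPM (SD, n = 3; log2 −2.86 ± 0.35, edgeR Benjamini-Hochberg adjusted p = 2.66e-06), and Gpihbp1, which anchors lipoprotein lipase in capillaries, from 1104 ± 98.1 to 338 ± 140.3 CPM (log2 −1.64). Together with Fabp4 (log2 −1.81) and Tcf15 (−1.68), 6 of 11 genes of endothelial fatty acid handling fell and 1 rose in both scopes of adjustment (camera adjusted p = 0.00509, adjusted p = 0.344 with an estimated correlation). Angiogenesis genes fell in 7 of 19 cases (9 over the list alone; adjusted p = 0.00522, adjusted p = 0.344 with an estimated correlation). Among these were the apelin gene Apln (log2 −1.93), Robo4 (−1.67), Egfl7 (−1.30) and Klf2 (−0.95). Cell cycle genes fell in 15 of 29 cases (23 over the list alone; adjusted p = 3.28e-09, adjusted p = 0.394 with an estimated correlation), such as Mki67 (log2 −1.09) and Cdk1 (−2.15). The largest rises were those of Fap (log2 3.18), Gxylt2 (3.13), Kcnt2 (3.10) and Slc13a3 (3.05), of which the first 3 stood higher in fibroblast-like nuclei, at 319.5, 358 and 1010.3 CPM at control P10. In the same libraries 15 of 29 matrix genes rose (20 over the list alone; adjusted p = 5.9e-07, adjusted p = 0.0602 with an estimated correlation), as did 17 of 18 calcium handling genes (18 over the list alone; adjusted p = 1.35e-15, adjusted p = 0.0743 with an estimated correlation), and Ttn went from 0.176% to 0.779% of UMIs. Large falls were those of Rpl29 (log2 −4.21) and the pseudogenes Rps26-ps1 (−4.31) and Rpl35a-ps7 (−4.29), uncertain for shared reads, and 46 of 52 ribosomal protein genes fell. Of 6308 genes 537 rose and 585 fell. The total of 1122 became 604, 696 and 411 without control P6 library 2, control P6 library 3 and control P10 library 3, and 369 with a term for sex, which ended the calls of Apln, Robo4, Egfl7, Klf2, Tcf15 and Rpl35a-ps7. Those of Fap, Egfl7 and Klf2 also ended without control P10 library 3. The total was 680 by the DESeq2 Wald test, 251 after thinning and 526 with at least 800 UMIs per nucleus.

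In KO endothelial-like nuclei 117 of 6308 genes rose and 33 fell. Nppa rose from 347 ± 325 to 19087 ± 14062 CPM (SD, n = 3; log2 5.71 ± 0.71, edgeR Benjamini-Hochberg adjusted p = 5e-06), followed by Myl7 (log2 4.38), the NAD salvage kinase gene Nmrk2 (4.29) and Acta1 (4.02), genes of heart muscle. Slc13a3 fell from 202 ± 42.1 to 40.5 ± 39.7 CPM (log2 −2.46), and Mcee (−3.98), C77370 (−3.69) and Slfn3 (−2.42) were lower. Matrix genes rose in 6 of 29 cases (9 over the list alone; camera adjusted p = 5.27e-06, adjusted p = 0.109 with an estimated correlation), including Ctgf (log2 3.17) and Lox (2.53). In these nuclei Hbb-bs went from 0.226% to 0.797% ± 0.761 of UMIs (1.67% in KO P10 library 2), Ttn from 0.779% to 1.06% and Malat1 from 5.002% to 2.599%, and 15 of 52 ribosomal protein genes rose. In the angiogenesis list 0 of 19 genes passed the edgeR test, with Nrp2 at log2 −0.94 (adjusted p = 0.130) and Cxcl12 at −1.19 (adjusted p = 0.163), and the list was lower (adjusted p = 0.0304, adjusted p = 0.324 with an estimated correlation). In the endothelial fatty acid list 0 of 11 passed, with Meox2 at log2 −0.82 (adjusted p = 0.199; list adjusted p = 0.811). The total of 150 became 23, 87 and 85 without control P10 library 3, KO P10 library 2 and KO P10 library 3, without which the calls of Mcee, C77370 or Slc13a3 ended, and 227 with a term for sex. It was 43 after thinning, 89 with no doublets left out, 31 with classes from marker UMIs and 78 without control P10 library 1 and KO P10 library 2 together.

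Endocardial-like nuclei changed the endothelin gene Edn1 in both comparisons. Edn1 (chromosome 13, 42301476 to 42307990), which encodes a vasoconstrictor peptide, fell from 1109 ± 754 to 155 ± 74.6 CPM with age (SD, n = 3; log2 −2.80 ± 0.50, edgeR Benjamini-Hochberg adjusted p = 0.00277) and rose to 849 ± 278 CPM in KO (log2 2.38 ± 0.49, adjusted p = 0.0263). Slc13a3 rose with age (log2 3.26) and fell in KO (log2 −2.97), and Cox7a1 fell in KO from 286 ± 79.0 to 56.0 ± 23.1 CPM (log2 −2.40). The muscle gene Cox7a1 also led the low-Malat1 cluster 5, which held 16.4% of nuclei at control P10 and 0.339% at KO P10. A part of free RNA in this fall was not tested. With age, Itih5 (log2 3.68), Dach1 (3.58) and Abca8a (3.33) rose and Ppp1r14b (−3.45), Gng5 (−3.12) and P4ha3 (−3.09) fell, while 7 of 46 respiratory chain genes fell (11 over the list alone; camera adjusted p = 1.76e-07, adjusted p = 0.525 with an estimated correlation) beside 29 of 44 ribosomal protein genes. Calcium handling genes rose in 10 of 17 cases (13 over the list alone; adjusted p = 1.84e-11, adjusted p = 0.273 with an estimated correlation) and sarcomere genes in 4 of 22 (4 over the list alone; adjusted p = 0.0158, adjusted p = 0.370 with an estimated correlation), while Ttn went from 0.104% to 0.580% of UMIs. In KO, Nppa (log2 5.97), Acta1 (4.36) and Efhd2 (2.40) rose and Slc26a10 (−2.32) and the potassium channel gene Kcnc2 (−2.12) fell, while Hbb-bs went from 0.157% to 0.546% ± 0.544 of UMIs (up to 1.17% in a single library) and Malat1 from 6.55% to 4.67%. Of 4401 genes 191 rose and 232 fell with age, and 20 rose and 10 fell in KO. The age total of 423 became 68 and 95 without control P6 library 2 and 3, 148, 681 and 172 without control P10 library 1, 2 and 3, 218 after thinning, 203 with at least 800 UMIs and 264 without control P10 library 1 and KO P10 library 2. The KO total of 30 lay between 5 and 92 when single libraries were left out, was 99 with a term for sex, and the KO calls of Edn1 and Efhd2 ended without control P6 library 2, control P10 library 3, KO P10 library 2 or KO P10 library 3.

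The genotype effect was compared between classes by interaction. It differed between cardiomyocyte-like and fibroblast-like nuclei for 187 of 11706 genes (edgeR with the library as a block), 104 with a higher and 83 with a lower log2 fold change in cardiomyocyte-like nuclei, and between cardiomyocyte-like and endothelial-like nuclei for 23 of 11383 genes, 13 higher and 10 lower. Among the genes named, the rises of Ryr3 (difference of log2 fold changes 2.75, Benjamini-Hochberg adjusted p = 0.00306), Trim47 (2.18, adjusted p = 0.000360) and Mthfd1l (1.37, adjusted p = 0.0466) were larger in cardiomyocyte-like than in fibroblast-like nuclei, and the fall of Rap1gap2 was deeper (−2.51, adjusted p = 0.00457), although Ryr3 and Rap1gap2 were too low for the fit of fibroblast-like nuclei alone. On the log2 scale, the rises of Nppb (−1.14, adjusted p = 0.00910) and Nmrk2 (−1.83, adjusted p = 0.0274) were larger in fibroblast-like nuclei. They started there from lower levels at control P10 and did not end higher. Nppb went from 94.4 to 1469 CPM in fibroblast-like and from 244 to 1662 CPM in cardiomyocyte-like nuclei. Nmrk2 went from 5.32 to 173 CPM and from 24.9 to 197 CPM in the same order. For Nppa the difference was −0.14 (adjusted p = 0.928) and for Acta1 −0.53 (adjusted p = 0.504). The number for fibroblast-like nuclei was 65, 102 and 97 without control P10 library 2, control P10 library 3 and KO P10 library 3, and 21 by limma. The number for endothelial-like nuclei was 1 without control P10 library 3 or KO P10 library 2, 2 without control P10 library 2, 60 and 13 without KO P10 library 1 and 3, 15 without a filter on low counts and 0 by limma.

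Shares of nuclei were compared library by library. Cardiomyocyte-like nuclei made up 52.5% ± 2.43 of nuclei at control P6, 44.2% ± 0.996 at control P10 and 36.2% ± 6.97 at KO P10 (SD, n = 3; two-sided exact permutation p = 0.1 and 0.2, adjusted p = 0.360 and 0.514, with 0.1 the smallest p that 3 against 3 libraries allow). Pericyte-like nuclei, the mural cells of capillaries, went from 2.68% ± 0.808 at control P10 to 0.967% ± 0.113 at KO P10, endocardial-like nuclei from 4.09% ± 0.892 to 7.78% ± 2.16 and macrophage-like nuclei from 2.33% ± 0.530 to 1.22% ± 0.380, each with exact permutation p = 0.1. By edgeR on the numbers of nuclei, pericyte-like nuclei fell (log2 −1.47, Benjamini-Hochberg adjusted p = 0.00523), macrophage-like nuclei fell (log2 −0.94, adjusted p = 0.0402), endocardial-like nuclei rose (log2 0.93, adjusted p = 0.0386), and cardiomyocyte-like nuclei differed by log2 −0.29 (adjusted p = 0.334). Endothelial-like nuclei made up 10.6% ± 4.75, 6.51% ± 3.25 and 3.88% ± 1.64, and fibroblast-like nuclei 16.3% ± 1.38, 17.0% ± 2.83 and 16.1% ± 3.67, in the 3 groups. When 3999 genes called in any comparison were left out of the clustering, 91.4% of nuclei kept their class. Shares were then 43.6% and 37.7% for cardiomyocyte-like, 2.51% and 0.842% for pericyte-like, 4.17% and 7.57% for endocardial-like and 2.78% and 1.81% for macrophage-like nuclei at control P10 and KO P10. The unnamed low-Malat1 clusters enter the denominator, and their share of 22.3% at control P10 and 33.2% at KO P10 can lower every named share. With named nuclei as the denominator, the share of cardiomyocyte-like nuclei differed by −1.86 points with age and −3.16 in KO. Counting the low-Malat1 cluster led by Acta1 and Nppa as cardiomyocyte-like left almost no KO difference in this share. Unnamed cluster 3, led by hemoglobin and macrophage RNA, held 4.23% of nuclei at control P10 and 23.5% at KO P10. Whether it holds macrophages was not tested, so the lower macrophage-like share is not a measured loss of macrophages.

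**Figure D4:**
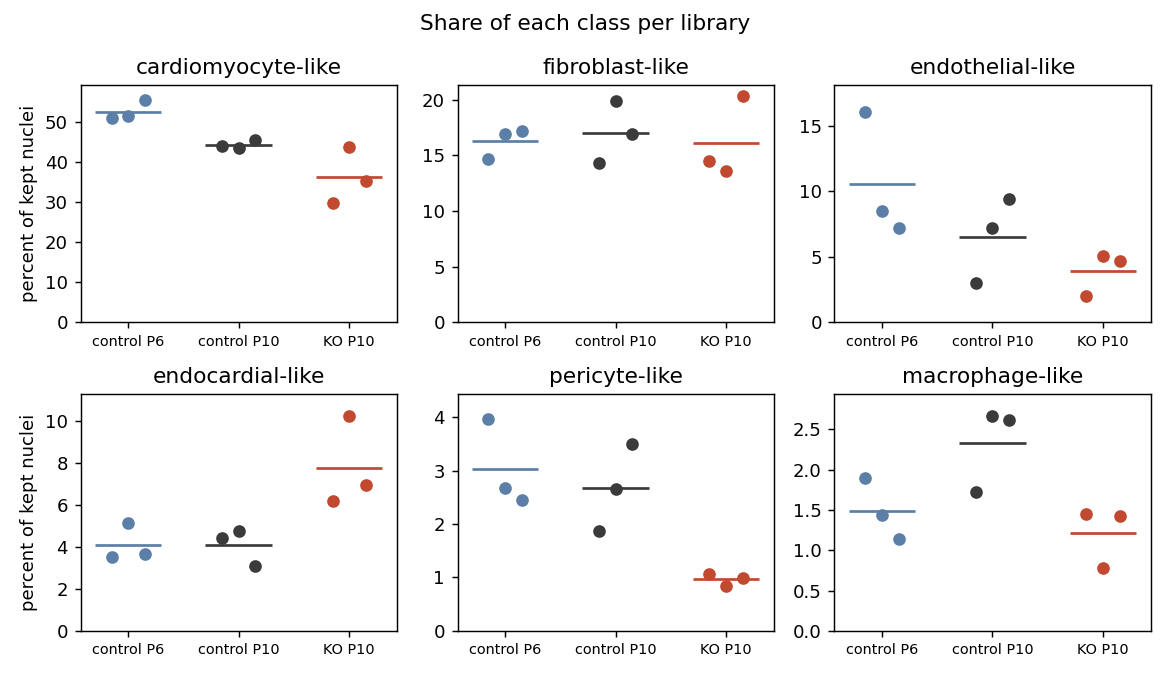
Percent of kept nuclei in each of 6 named classes, with 1 point per library and a line at the mean of each group. Pericyte-like shares averaged 2.68% at control P10 and 0.967% at KO P10, without overlap between their libraries.

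Sums over all barcodes of a library, which need no clustering but mix composition with expression, gave 1717 genes higher and 2076 lower at control P10 than at control P6, and 1500 higher and 1087 lower in KO, of 15841 tested (edgeR, Benjamini-Hochberg). These sums keep the barcodes shared by KO P10 libraries 1 and 2, and without them 3140 genes differed with age and 1855 in KO. In these sums the KO change of Esrra was log2 −2.92, of Esrrg −1.13, of Ppara −2.63, of Cox7a1 −2.21, of Nppa 5.43, of Acta1 4.01 and of Gdf15 3.72. With age, the change of Pdzrn4 was log2 3.23 and that of Tnni1 −1.87. The total of 3793 with age became 2033, 2022 and 2496 without control P6 library 2, control P6 library 3 and control P10 library 3, and the total of 2587 in KO became 843 and 1555 without control P10 library 3 and KO P10 library 3.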

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

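For the patterns weighed here, the tests of shared controls and of the shared barcodes were chosen after those results had been seen, as was the rule that leaves the test of free RNA undecided; the other tests were chosen before.

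Of 408 genes that passed both with age and in KO in cardiomyocyte-like nuclei, such as Rgs7 and Gdf15, 364 had opposite directions. Sharing of the control P10 libraries stays open as a cause. The covariance lay −0.139 beyond that of simulated unchanged groups, although r and rho (−0.306 and −0.336) were weaker than theirs (−0.492 and −0.469). Each simulated gene was drawn independently, so the simulated spread leaves out shifts shared by many genes and cannot decide. Cytoplasmic RNA carried with nuclei stays open as well. The difference was −0.145 in the 2981 genes lowest in droplets low in Malat1, past the simulated spread that this cause was predicted to keep within. CPM are shares of a total, so carried RNA would also lower these genes, by amounts that differ among them, and the test cannot decide. The medians of these genes, log2 0.28 with age and −0.25 in KO, and of the 2981 highest, −0.35 and 0.38, go with cytoplasmic RNA. Delayed maturation of KO cardiomyocytes was not tested, since KO libraries at a second age would be needed, and stays open beside the uneven sex of control P6 and control P10.

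Genes such as Nppa, Acta1 and Myl7 rose in KO in cardiomyocyte-like, fibroblast-like and endothelial-like nuclei alike: 62 genes, of which 46, Rplp0 among them, were left after other ribosomal protein genes and predicted genes were set aside, and 4 of these differed in KO effect between cardiomyocyte-like and fibroblast-like nuclei. Free RNA in the droplets cannot be told apart: the level in KO fibroblast-like nuclei lay below that in KO droplets low in Malat1 (median log2 ratio −1.48), but Nppa, Acta1 and other genes of the pattern lead the clusters of that reference. Cardiomyocyte nuclei among the other classes are argued against: 15 cardiomyocyte markers stood in KO fibroblast-like nuclei at a median of 27.9% of their cardiomyocyte level (highest 82.2%), but the genes of the pattern at 120% and Nppa at 121%. The 46 also hold Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, hemoglobin genes that fibroblasts lack, which goes with free RNA, and for the others expression by these cells and the part of free RNA stay open.

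KO P10 libraries 1 and 2 shared 465 barcodes, against at most 12 in any other of 36 pairs of libraries, a signal outside the comparisons. Chance reuse is argued against by that number and by the profiles, which correlated at a median of 0.787 for the same barcode and 0.426 between different shared barcodes. Nuclei of library 1 counted in both fits, since the shared barcodes held 883 of the 889 Xist UMIs of library 2 (99.3%) and 16.8% of its UMIs. No biological explanation was tested. How the barcodes came to be in both libraries stays open.

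Other results differed between groups or lay in data outside the comparisons. The KO effect differed between cardiomyocyte-like and fibroblast-like nuclei for 187 genes and between cardiomyocyte-like and endothelial-like nuclei for 23 genes. For Hmcn2, which fell in fibroblast-like nuclei, the log2 fold change was higher in cardiomyocyte-like nuclei by 4.43, for Ryr3 by 2.75, for Trim47 by 2.18, for Mthfd1l by 1.37 and for P4ha1 by 1.05. Hmcn2 was low in cardiomyocyte-like nuclei, at 16.8 CPM at control P10 and 12.0 CPM at KO P10. In fibroblast-like nuclei it stood at 299.9 and 8.81 CPM. For Rap1gap2 the difference was −2.51 and for Nppb −1.14. Of KO P10 nuclei, 23.5% lay in unnamed cluster 3, led by Pf4 and Hba-a1, and 9.43% in unnamed cluster 8, led by Acta1 and Nppa, against 4.23% and 1.66% at control P10.

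Regrouping 6 libraries of 3 against 3 gives 10 splits, too few for a share under 0.05. In cardiomyocyte-like and fibroblast-like nuclei, for both comparisons, the real split alone (1 of 10) reached its number of genes called, and every other gave 0 by edgeR. In endothelial-like nuclei this was also 1 of 10, with at most 0 for age and 1 for KO in the others, in endocardial-like nuclei 1 of 10, with at most 0 and 3, and in sums of all barcodes 1 of 10, with at most 0 and 1. Among splits giving 0, the edgeR counts with unadjusted p under 0.05 reached 1675 for age and 1022 for KO in cardiomyocyte-like nuclei and 1378 and 748 in fibroblast-like nuclei. For the lists, 4 of 10 splits called as many as the 7 real ones for age, with up to 10, and 1 of 10 as many as the 13 for KO, with up to 9 in the others. For the difference between classes the real split was 1 of 10, with at most 2 genes for fibroblast-like and 6 for endothelial-like nuclei in the others.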

How the results depend on the processing

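No fold change of a named gene called in the main analysis changed sign under an alternative, while the uncalled changes of Ppargc1a and Myh7 in cardiomyocyte-like nuclei did in some. The causes of the changes below were not tested unless fewer libraries, nuclei or UMIs are named. Differences in the share of cardiomyocyte-like nuclei stayed negative but not of one size: −9.10 to −6.92 points with age and −11.7 to −4.82 in KO without single libraries, −1.86 and −3.16 with named nuclei as the denominator, and −7.46 and −0.267 with the low-Malat1 cluster added. A test whose smallest p is 0.1 could not pass in any of them. The share of endocardial-like nuclei with age went from −0.0126 to 0.268 points when clustering left out the genes called. Esrra kept its call, at −2.661 to −2.0003 in cardiomyocyte-like nuclei and with a deeper fall in sums over all barcodes, given above. Among genes named, 4595 of 4998 alternative values stayed on their side, 316 lost and 87 gained a call. The balance of genes higher and lower is no fixed direction: with age it was 1074 to 1148 in cardiomyocyte-like nuclei but 1048 to 975 by the DESeq2 Wald test and 1198 to 1124 with the sex term, and 537 to 585 in endothelial-like nuclei but 864 to 817 at Leiden resolution 0.5. In KO endocardial-like nuclei it was 20 to 10 but 2 to 3 without KO P10 library 3. Low depth may limit the smaller classes, and thinning lost most calls in endothelial-like nuclei. Alternatives that use sex, shared barcodes, several libraries left out together or changed clusters were chosen after the data were examined.

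Without single libraries, the genes called ranged from 878 to 2652 with age and 428 to 1435 in KO in cardiomyocyte-like nuclei, 302 to 1548 and 58 to 350 in fibroblast-like, 411 to 1301 and 23 to 224 in endothelial-like, 68 to 681 and 5 to 92 in endocardial-like nuclei, and 2022 to 4569 and 843 to 2826 in sums of all barcodes. The lists called ranged from 4 to 8 and 10 to 13, the genes differing between classes from 65 to 272 (fibroblast-like) and 1 to 60 (endothelial-like), the correlation from −0.469 to −0.231, and Esrrg from −1.26 to −0.95. With fewer libraries the tests have less to estimate spread from.

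In the order age then KO where both moved, classes from marker UMIs gave 1370 and 819 (cardiomyocyte-like), 270 and 33 (fibroblast-like), 31 for KO (endothelial-like) and 129 for KO (endocardial-like). At least 800 UMIs gave 510 and 121 (fibroblast-like), 526 for age (endothelial-like) and 203 for age (endocardial-like). Thinning gave 602 for age (fibroblast-like), 251 and 43 (endothelial-like), and 218 and 17 (endocardial-like). No filter on low counts gave 379 for KO (fibroblast-like), 98 for KO (endocardial-like) and 15 for the difference between cardiomyocyte-like and endothelial-like nuclei. No doublets left out gave 89 and 85 for KO (endothelial-like and endocardial-like), Leiden resolution 0.5 gave 72 for KO (endocardial-like), and the DESeq2 Wald test 680 for age (endothelial-like). The sex term gave 497 for age (fibroblast-like), 369 and 227 (endothelial-like) and 99 for KO (endocardial-like). Control P10 library 1 and KO P10 library 2 left out together gave 71 and 78 for KO (fibroblast-like and endothelial-like) and 264 for age (endocardial-like). Shared barcodes kept gave 72 for KO (endocardial-like), and the low-Malat1 cluster added 2335 for KO (cardiomyocyte-like).

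Camera with an estimated correlation called 0 lists for age (2 of 15 with unadjusted p under 0.05) and 0 for KO (4 of 15), while fry called 5 and 4. Limma called 21 genes for the difference from fibroblast-like nuclei and 0 for that from endothelial-like nuclei (748 with unadjusted p under 0.05), against 187 and 23 by edgeR. Genes of at least 50 CPM gave a correlation of −0.394.

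The replicate number as a block moved the KO calls to 239 in endothelial-like and 85 in endocardial-like nuclei and no other count by over 1.5 times. Same-numbered libraries correlated at −0.124 to 0.234 in their deviations, and not every library correlated best with its own number, so the numbers do not pair the libraries.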

Other observations

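Cycling cardiomyocyte-like and fibroblast-like nuclei were fewer in KO P10 library 2 than in any other library. In KO P10 library 2, 0 of 1286 cardiomyocyte-like nuclei lay in the cluster led by cell cycle genes such as Ect2 (up to 0.233% allowed by the count), against 4.51% to 15.9% in the other libraries. For fibroblast-like nuclei 2 of 400 (0.5%) lay in the cluster led by Neil3 and Top2a, against 3.42% to 20.9%. Mki67 stood at 8.07 CPM in cardiomyocyte-like nuclei of that library and at 104 to 239 CPM in the others. Cell cycle values of the KO group include this library.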
